A study of Homo sapiens with 77 samples.

How the data were processed

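RNA from MCF7 cells was hybridized to Affymetrix U133 Plus 2.0 arrays, 77 in all. Per the labels' protocols, cells were transfected with 30 nM siRNA using a lipid reagent, fewer cells were seeded for the 96 h time than for 48 h, RNA was prepared with TRIzol and columns, and biotin-labelled cRNA was made in a single cycle. The protocols also name a qRT-PCR assessment of knockdown, not used here. Deposited values are signal intensity values from MAS5, per the submitters' processing notes, whose version is not given in the sources used here, scaled by the authors on the linear scale. The trimmed mean signal (2 percent trimmed at each end) was near 500.07 in every array, and no logarithm had been taken. The 77 columns matched the 77 labelled samples, and no pair of columns was identical (highest correlation between arrays 0.979).

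Groups followed the labels: target and time (36 groups of 68 arrays), scramble siRNA at 48 h and 96 h (3 arrays each) and untreated cells (3). The design text says that 2 siRNA sequences were used per target. The labels call the arrays of a group biological replicates and do not say which sequence each received, so whether replicates differ by sequence, and how independent they are, is not known here. Groups of 2 (32) and of 1 (4) limit precision, and a lone array was assumed to vary like the arrays of other groups.

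Values were taken as log2 of signal plus 16. Of 54675 probe sets, 41097 carried a single gene symbol in the reference table, 1801 several symbols and 11777 none, and 62 were controls. For each of 19775 genes the probe set with the highest mean log2 value over all arrays was used, and genes were kept when that mean reached the median of all probe sets (signal 63.3), which left 12088. The signal filter limits what could be tested to the brighter part of the transcripts. A gene kept by its mean over all arrays could still lie below that level in a single group, where the size of a change depends on the pseudocount. MAP2K7 and MAPK14 had no probe set with a listed symbol of their own and NME2 shared its probe sets with another gene, so their levels were not analysed here. Genes on the Y chromosome and XIST were left out of the named genes.

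A linear model with 39 group means and 38 residual degrees of freedom was fitted with limma 3.58.1 in R 4.3.3, with moderated variances following the trend with level. All p values without the word exact or permutation come from limma or its gene-set tests, adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. Comparisons were each target's own transcript against time-matched scramble; each target against scramble and against the mean of the other targets at the same time, averaged over times; the mean of all targets against scramble at each time and the difference of the 2 times; 96 h against 48 h over the 17 targets with both times and in scramble; and scramble against untreated cells. Adjustment over the list alone was made within the targets or within a gene list. Targets read in other targets' knockdowns were adjusted over all such pairs. They were read again, by a choice made after the values were seen, with the gene's own knockdown left out of the comparison. Untreated cells have no time in the labels and served for both times.

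A total of 34 gene lists was written before the data were examined, and 31 with at least 5 tested genes were tested. These were the targeted suppressors, p53 targets, mitosis, DNA replication, histones, estrogen response, luminal epithelial, mesenchymal, basal mammary, interferon response, NF-kB response, ATF4 response, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, heat shock, NRF2 targets, immediate early genes, ERK feedback, Wnt, YAP and TGF-beta targets, invasion, cell junctions, apoptosis regulators, small RNA machinery, lysosome, ribosomal proteins, oxidative phosphorylation, metallothioneins and antigen presentation. Fibroblast, leukocyte and endothelial markers had too few tested genes. Lists were tested with camera at a preset correlation of 0.01, with camera's correlation estimated per list, and with fry. Median, mean and test had the same sign in all 149 called lists.

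Similarity of knockdown arrays was the correlation across genes of deviations from the mean of the knockdown groups of the same time, tested by permuting target labels within a time (10000 permutations, one-sided). For the families of kinases and cadherins it was the correlation of the targets' changes against the other knockdowns (100000 permutations of the targets, one-sided). Because targets shared control arrays, recurrence across targets was compared with 20 simulated sets in which no knockdown changed a gene and the scramble arrays were shared. In each set the deviations of the scramble arrays were drawn with replacement and random signs. An outlying scramble array could thus enter more than once, and arrays of one target and number were drawn independently.

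Replicate numbers were checked for pairing before a block was used. Deviations of scramble arrays with the same number at 48 h and 96 h correlated at 0.29, 0.60 and 0.26, each over 0.1. Values with and without a block are thus given. Arrays 1 at 48 h and 3 at 96 h also correlated (0.36), as did 3 and 1 (0.23), so pairing showed for number 2 alone. The other combinations lay between -0.49 and -0.36. Same-number scramble and untreated arrays lay between -0.05 and 0.18 and were not paired. In the knockdowns 11 of 14 targets with 2 arrays at both times had a same-number correlation over 0.1. Their block values are with the settings.

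Named genes were chosen by a rule written before the data were examined. It took the 19 targets with NDRG1 and NME2; for all targets against scramble, up to 10 rises and 10 falls called at both times, or at either time with the same sign at the other where fewer than 5 passed; up to 8 each way for time in the knockdowns and for scramble against untreated cells, the latter by the same fallback; the 3 largest each way for the 8 targets with most calls and the largest each way for the others; up to 4 called members of a described list; and the 10 genes called in most targets each way. Targets and genes without a unique symbol were left out of all but the first part, except where the list is the targets.

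The model was tested on simulated data with independent Gaussian noise, 12088 genes and 50 changed genes per fold. At folds of 1.5, 2, 3 and 4, the percent recovered was 58, 90, 100 and 100 for a target with 4 arrays against scramble and 72, 96, 100 and 100 against the other targets. It was 44, 80, 98 and 100 for a target with 2 arrays at a single time (AKAP12) and 54, 88, 100 and 100 for 1 array at each time (CD44), both against the other targets. All targets against scramble gave 54, 90, 100 and 100 at 48 h and 60, 88, 100 and 100 at 96 h, and the difference of times 30, 76, 96 and 96. Time gave 98, 100, 100 and 100 in the knockdowns and 44, 68, 100 and 98 in scramble. Scramble against untreated cells gave 44, 78, 100 and 100 at 48 h and 34, 78, 96 and 100 at 96 h. False calls numbered 1 to 13 per comparison. Of the lists, the 1 planted was recovered and 0 of 30 unchanged were called.

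Alternatives written before the data were examined were quantile normalization, pseudocounts of 1 and 64, no filter or the upper 30% of probe sets, the mean of all probe sets of a gene, no variance trend, array weights, the samples of a comparison alone, replicate blocks, leaving out each array, untreated cells as the control and, for the average of targets, only those whose own transcript fell. Others were added later and are named where their effect is given.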

Results

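Expression was profiled in MCF7 cells, an estrogen receptor-positive line from a human breast tumor, after siRNA transfection against 19 genes that the labels call metastasis suppressors. The 19 targets were AKAP12, ARHGDIB, BRMS1, CASP8, the CD44 and CD82 genes, the cadherins CDH1, CDH2 and CDH11, DRG1, GSN, KISS1, the kinases MAP2K4, MAP2K6, MAP2K7 and MAPK14, NME1, PEBP1 and RRM1. The series title frames the question as which genes move opposite to several suppressors at once. The 77 arrays were 68 of knockdowns in 36 groups of target and time, 3 of scramble siRNA at each of 48 h and 96 h, and 3 of untreated cells with no labelled time. Of the knockdown groups, 32 held 2 arrays and 4 held 1 (CD44 at both times, CDH1 at 96 h and CDH2 at 48 h). AKAP12 was measured only at 96 h and KISS1 only at 48 h.

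Every array had a trimmed mean signal between 500.066 and 500.079, and the median signal lay between 59.6 and 80.8. Array 2 of the ARHGDIB knockdown at 96 h had the lowest median signal, the lowest GAPDH 3' to 5' log2 ratio (-0.33) and the largest distance from the other arrays of its time (root mean square 0.872 log2 units against a median of 0.259 over arrays). The highest ACTB 3' to 5' log2 ratio (2.43, median 0.93) belonged to array 2 of the CD82 knockdown at 96 h. Array 1 of the AKAP12 knockdown had the highest GAPDH ratio (0.12). Correlations between arrays of the same group (median 0.972 across probe sets) were close to those between groups (0.971).

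The targeted transcripts came first, since they check the labels. Of the 17 targets with a probe set of their own, 13 fell against time-matched scramble cells (adjusted over the list alone, and also 13 adjusted over all genes). The largest falls were those of DRG1, a GTP-binding protein (-2.64 log2 units, SE 0.19, 16.1% of scramble), NME1, a nucleoside diphosphate kinase (-2.39, SE 0.18), and GSN, the actin-severing protein gelsolin (-2.34, SE 0.18; n = 4 knockdown and 6 scramble arrays for each). PEBP1, an inhibitor of Raf kinase signaling, was left at 21.9%, BRMS1 at 25.8%, CD44, the hyaluronan receptor, at 29.8% (n = 2) and CASP8, an initiator caspase, at 32.2%. AKAP12 (34.7%, n = 2), MAP2K6 (35.2%), ARHGDIB (38.0%), RRM1, the large subunit of ribonucleotide reductase (47.7%), CDH1, E-cadherin (48.8%, n = 3), and MAP2K4 (52.0% at 48 h and 48.2% at 96 h) fell less. CDH1 was at 71.6% at 48 h (n = 2) and 33.3% at 96 h, where a single array has no spread of its own, so no p value is given for the difference between times. The targets that did not pass were CDH11 (68.8% of scramble; -0.54, SE 0.28), CD82, a tetraspanin (78.9%; -0.34, SE 0.35), CDH2, N-cadherin (-0.25, SE 0.40), and KISS1, the kisspeptin precursor (0.84, SE 0.49). CDH2 and KISS1 lay below the level of the signal filter, where a fall could hardly be seen. In scramble cells CD82 (6.60 at 48 h and 6.58 at 96 h) and CDH11 (6.43 and 6.60) lay just above that level. Other probe sets of CDH11 were between -1.07 and -0.15. Those of AKAP12 (-1.09 to 0.45) and ARHGDIB (-0.21 and 0.56) lay below that level and went both ways. CDH11 did fall against the other knockdowns (adjusted p = 0.000311 over the list alone). In 8 knockdowns the target was the most strongly lowered of all genes tested against the other knockdowns. The transcripts of MAP2K7, MAPK14 and NME2 were not analysed here.

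**Figure D1:**
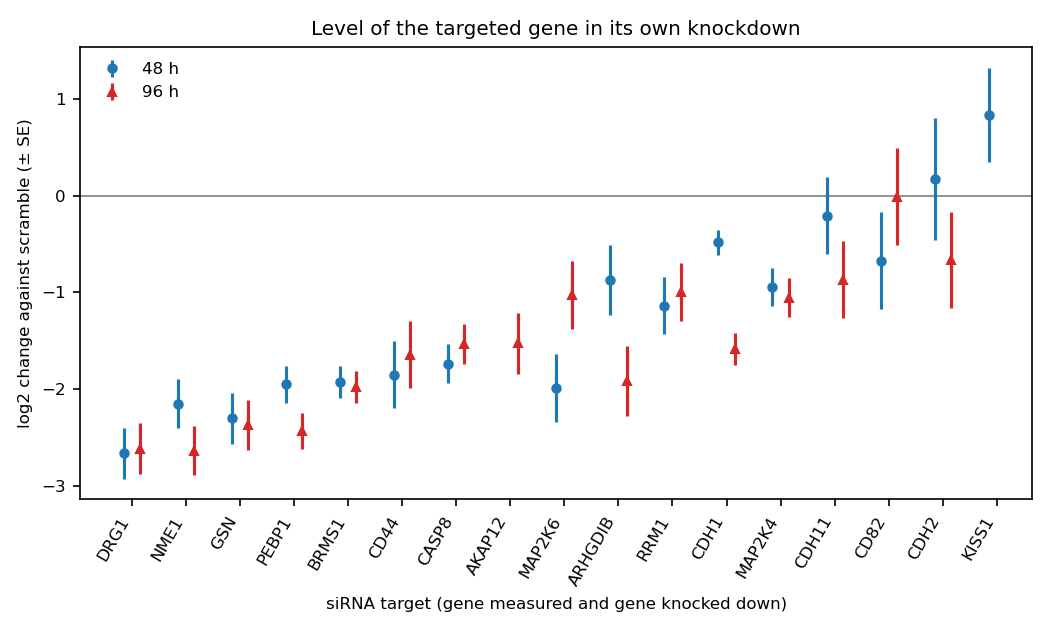
Log2 change of each targeted transcript in its own knockdown against time-matched scramble cells, with the standard error as bars and the 2 times shown apart, for the 17 targets with a probe set listed under their own symbol. DRG1 (-2.64 over both times), NME1 (-2.39) and GSN (-2.34) lie lowest and KISS1 (0.84) lies above 0.

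The DRG1 symbol has also been used for NDRG1, a stress-responsive gene, so NDRG1 was read in the same cells. NDRG1 was at -1.15 log2 units against scramble in the DRG1 knockdown (SE 0.33, adjusted p = 0.12) and at -0.27 against the other knockdowns (SE 0.26, adjusted p = 0.918). Among the other targets read in each knockdown, 3 transcripts passed as higher than in the other knockdowns, in 4 pairs. The other knockdowns include the one aimed at the transcript read, which raises such values, so each was read again without it. MAP2K6 rose by 1.01 log2 units (SE 0.20, adjusted p = 0.00166), and by 0.90 without its own knockdown (adjusted p = 0.00983), in cells given siRNA against MAPK14, the p38 kinase that MAP2K6 phosphorylates. BRMS1, a subunit of histone deacetylase complexes, rose by 0.69 (SE 0.13, adjusted p = 0.00108), and by 0.60 without its own knockdown (adjusted p = 0.00983), in the AKAP12 knockdown. GSN, at 0.55 with CD82 siRNA and 0.59 with RRM1 siRNA, did not pass without its own knockdown (0.43 and 0.47, adjusted p = 0.181 and 0.119), whereas NME1 with CDH2 siRNA passed only in that reading (-0.68, adjusted p = 0.033).

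**Figure D2:**
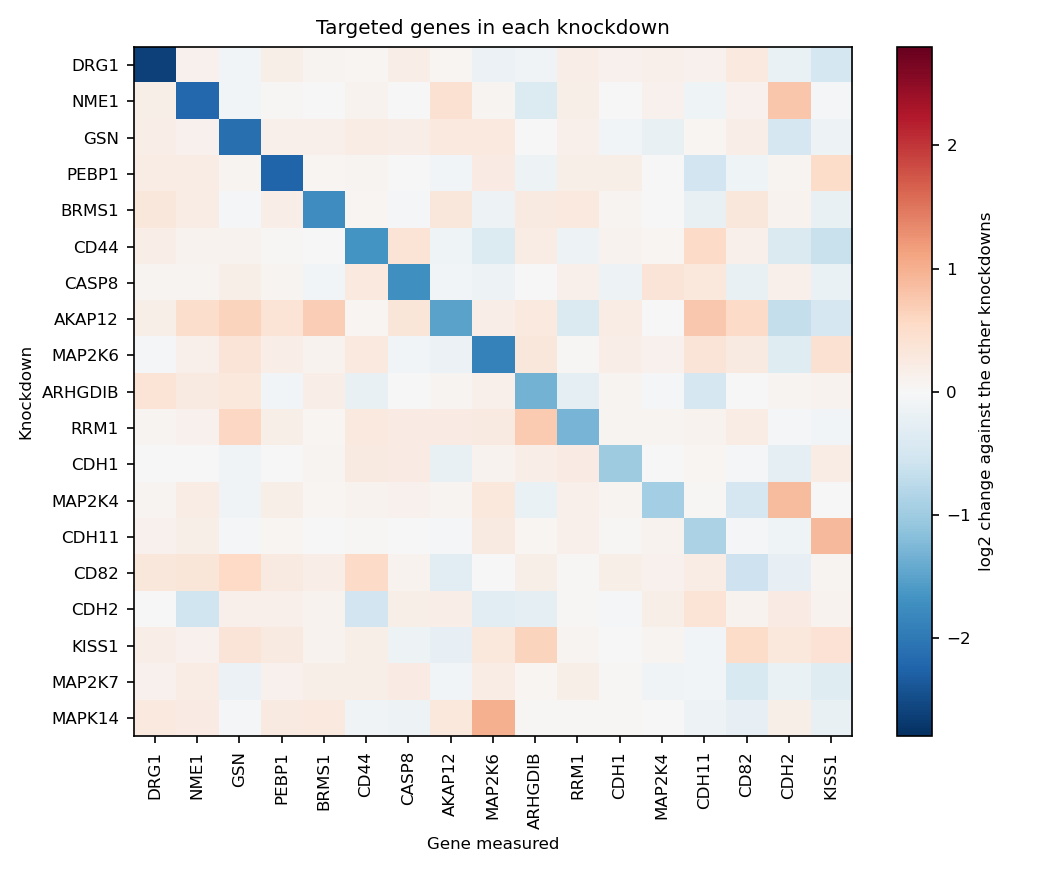
Log2 change of each targeted transcript (columns) in each knockdown (rows) against the other knockdowns at the same time. The diagonal holds the targets' own falls, which also enter the comparison of the other rows, and the strongest called rise off it is MAP2K6 in the MAPK14 knockdown (1.01).

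Against scramble cells, the counts of changed genes differed widely between targets. Apart from the targets themselves, 766 genes changed with ARHGDIB siRNA (269 higher, 497 lower), 388 with CD82 siRNA (183 higher, 205 lower), 224 with CD44 siRNA (102 higher, 122 lower) and 61 in the AKAP12 knockdown (19 higher, 42 lower). DRG1 siRNA gave 20, MAPK14 15, KISS1 13, CDH2 10, CASP8 7, RRM1 6, and MAP2K6 and MAP2K7 1 each. NME1, BRMS1, CDH1, CDH11, MAP2K4, GSN and PEBP1 gave 0 in limma, with between 819 and 1405 genes at an unadjusted p under 0.05. The sum over the 19 targets was 1525 (592 higher, 933 lower, own genes included). It was 383 when arrays of one target with the same number were allowed a shared random effect. It became 579 without array 2 of scramble at 48 h, 598 without array 2 and 3142 without array 3 of scramble at 96 h, and 717 without array 2 of ARHGDIB at 48 h. Leaving out array 1 of ARHGDIB at 96 h raised it to 5071, and leaving out array 2 of that group took the ARHGDIB calls to 0. Without array 1 of the AKAP12 knockdown its count was 0, and without array 2 of CD82 at 96 h that of CD82 was 110. That of CD44 was 17 without its 96 h array and 394 without array 3 of scramble at 96 h. The smaller counts also moved, own genes included. With 1 array left out the lowest were 0 for CDH2, MAPK14, RRM1, KISS1, MAP2K6 and MAP2K7, 1 for CASP8 and 3 for DRG1. Without array 3 of scramble at 96 h they were 380 for DRG1, 232 for CDH11, 202 for CASP8, 100 for RRM1, 89 for MAP2K6, 77 for PEBP1, 64 for CDH2, 11 for NME1 and 7 for MAP2K4. Without an array of their own they reached 499 for KISS1, 411 for MAPK14 and 28 for BRMS1. The order of the targets depended on the settings too. Against untreated cells AKAP12 had 1906, CD82 200, CD44 123, KISS1 87 and ARHGDIB 24, and with array weights CD44 had 526, CASP8 79, CD82 25, ARHGDIB 13 and AKAP12 0.

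No gene was called higher in at least 10 of the 19 knockdowns, and none lower (0 and 0 by limma), and none was called one way in 5. Without array 3 of scramble at 96 h, 1 gene was called higher in at least 10. With a replicate block, genes reached that number in both directions, as given with the settings below. The per-target tests behind these counts had between 819 and 2810 genes each at an unadjusted p under 0.05. CDADC1, which carries a deaminase domain, was higher in 4 knockdowns (CD82, MAPK14, ARHGDIB and CD44), above scramble in 19 of 19 and by 0.46 log2 units on average. MYC, the growth-promoting transcription factor, was lower in 4 (CDH2, CASP8, MAP2K6 and ARHGDIB), below scramble in every knockdown and by -0.58 on average. CARMIL3, MMP16, a membrane-bound metalloproteinase, and SLX4, a scaffold of DNA repair nucleases, were each higher in 3 knockdowns. CRISPLD2, B3GNT5, GDAP2, SPRED2, an inhibitor of ERK signaling, and ASAP1 were each lower in 3. Among genes called in 2 knockdowns, ZNF137P, ENPP5, ABCA12, TNFRSF11B, BLNK and BMP5 were higher, and NDRG1 (CD82 and CD44), RCN1, TP53INP1 and PGBD5 lower. All targets shared the same 3 scramble arrays per time. The 50 genes higher and 49 lower in at least 2 knockdowns compare with 9.55 and 22.8 for independent lists, and with 364 (range 0 to 2211) and 376 (0 to 2275) in 20 simulated sets of unchanged knockdowns against shared controls. The mean covariance between targets was 0.0221, against 0.0258 simulated (0.00471 to 0.0995), and the mean correlation 0.409 against 0.403. Part or all of the recurrence may therefore come from the shared controls. All 19 knockdowns were above scramble for 281 genes and below for 268, against 561 and 579 simulated.

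With all targets averaged, a single gene differed from scramble at 48 h, and 6 at 96 h, where CD36, RAD50, MYCBP2, MTERF2 and CDC40 were higher and MYC lower. CD36, a fatty acid receptor, was 1.13 log2 units higher at 96 h (SE 0.23, adjusted p = 0.0276, 2.19-fold) and 0.31 higher at 48 h (adjusted p = 0.936). Its log2 level was 5.89 ± 0.60 (SD, n = 3) in scramble cells at 96 h and 6.46 ± 0.12 in untreated cells. The former lies below the level of the signal filter, so the size of the rise depends on the pseudocount. SLX4 was 0.86 higher at 48 h (SE 0.15, adjusted p = 0.0134) and 0.12 at 96 h (adjusted p = 0.759). Its log2 level was 7.01 ± 0.67 (SD, n = 3) in scramble cells at 48 h, 7.93 ± 0.22 at 96 h and 7.95 ± 0.26 in untreated cells. MYC was 0.46 lower at 48 h and fell by 0.72 at 96 h (SE 0.14, adjusted p = 0.0276), and it also passed in the mean of both times (-0.59, SE 0.10, adjusted p = 0.00711). MYCBP2, a ubiquitin ligase, and MTERF2, of the mitochondrial transcription termination factor family, rose by 0.62 (SE 0.12) and 0.55 (SE 0.12) at 96 h. RAD50, a DNA repair protein (0.94, SE 0.19, adjusted p = 0.035), and CDC40, a splicing factor (0.51, SE 0.10), fell outside the naming rule and were chosen after their values were seen. At an unadjusted p under 0.05 there were 585 genes at 48 h and 1723 at 96 h.

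The scramble controls themselves set several of these values. Against untreated cells instead of scramble, MYC was at 0.22, MYCBP2 at -0.25 and MTERF2 at -0.13 over both times, all with the opposite sign. At 96 h alone, the mean MYC level of the knockdowns (11.37) lay below that of untreated cells (11.52) as well. RAD50 was at 8.99 in scramble at 96 h and at 10.31 in untreated cells, so its rise against scramble did not reach the untreated level. The MYC call over both times ended without array 2 of scramble at 48 h (-0.49) or at 96 h (-0.44). The number of genes called at 96 h was 0 without array 1 of scramble at 96 h, 1 without array 2 and 1040 without array 3. It became 56 and 33 without array 1 and array 2 of ARHGDIB at 96 h, and 56 without either KISS1 array, which alter only the spread. At 48 h the count was 0 without array 2 of scramble and 2 without either ARHGDIB array of 96 h. The difference between the 96 h and the 48 h response passed for 0 genes in limma (877 at an unadjusted p under 0.05), with 96 called without array 3 of scramble at 96 h, and 1 without array 1 at 48 h or array 2 at 96 h.

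Gene lists moved together in these averages by camera with its preset correlation, 11 at 48 h and 14 at 96 h, though none of the 25 held with an estimated correlation. At 48 h, genes of mitosis (median 0.23, 21 of 23 above 0), DNA replication (0.22, 23 of 25) and the histones (0.36, 11 of 11) rose against scramble, with adjusted p = 0.478, 0.447 and 0.305 with an estimated correlation. Of these, 4 histone genes passed adjusted over the list alone, and 0 genes of the other lists. Targets of p53 (-0.24), TGF-beta (-0.28) and YAP (-0.12), the ATF4 response (-0.18), NRF2 targets (-0.06), immediate early genes (-0.11) and invasion genes (-0.21) fell, with adjusted p between 0.265 and 0.478 with an estimated correlation. The targeted suppressors as a list were at -0.10 (adjusted p = 0.265 with an estimated correlation), a value to which each target's own knockdown contributes, and at -0.02 with each read without it. A single immediate early gene passed adjusted over the list alone, and 0 members of the rest. At 96 h the 25 ribosomal protein genes lay below scramble without exception (median -0.32, 21 passing adjusted over the list alone, adjusted p = 0.244 with an estimated correlation), but their median was 0.00343 after quantile normalization. Genes of hypoxia and glycolysis (-0.23, 1 of 27 above 0), ERK feedback (-0.30, 1 of 12), ATF4 (-0.25, 2 of 20), NRF2 (-0.22, 1 of 17), immediate early (-0.17, 1 of 17) and TGF-beta response (-0.27, 1 of 12) fell. Their counts adjusted over the list alone were 1, 4, 1, 2, 3 and 0, and their adjusted p = 0.163, 0.108, 0.244, 0.244, 0.186 and 0.364 with an estimated correlation. Interferon-response genes (0.39, 18 of 23 above 0, 5 adjusted over the list alone), histones (0.31, 10 of 11, 0) and mitosis genes (0.12, 18 of 23, 0) rose, with adjusted p = 0.24, 0.393 and 0.541 with an estimated correlation. Unfolded protein response genes (-0.15, 2 adjusted over the list alone), p53 targets (-0.15, 0), luminal epithelial genes (-0.16, 1) and oxidative phosphorylation genes (-0.07, 0) fell, with adjusted p between 0.244 and 0.601 with an estimated correlation. The luminal and oxidative phosphorylation medians turned to 0.03 and 0.00625 after quantile normalization, which also ended the calls of the p53 and unfolded protein response lists (adjusted p = 0.0583 and 0.0559).

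The direction of several lists turned with the choice of control arrays. Against untreated cells, mitosis genes were lower at 48 h (median -0.15, adjusted p = 0.00431) and at 96 h (-0.28, adjusted p = 8.84e-12), while interferon-response genes were higher at 96 h in either comparison (0.35, adjusted p = 1.3e-10). Ribosomal protein (-0.30), luminal epithelial (-0.15) and unfolded protein response genes (-0.09) also kept their call and direction at 96 h. Quantile normalization ended these 3 calls against scramble and was not applied here. In the order given, adjusted p = 0.785, 0.272, 0.0586, 0.272, 0.0753 and 0.32 with an estimated correlation. Without both scramble arrays numbered 2, genes of mitosis (-0.10) and DNA replication (-0.09) were lower at 48 h and ATF4 genes higher (0.10), each called and opposite to that with all arrays, but with adjusted p = 0.686, 0.686 and 0.234 with an estimated correlation. At 96 h the interferon-response genes alone kept their call and direction (0.24, adjusted p = 2.47e-06, and 0.181 with an estimated correlation).

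To compare the targets without scramble arrays, each was set against the mean of the others at the same time, and 5259 calls resulted over the 19 targets (2220 higher, 3039 lower). AKAP12 had 2577 apart from its own gene, ARHGDIB 1552, CD82 739, CD44 207, KISS1 78, DRG1 23, CDH2 21, RRM1 17, MAPK14 14, BRMS1 7, PEBP1 6, CDH11 4 and MAP2K6 1. NME1, CDH1, CASP8, MAP2K4, MAP2K7 and GSN had 0 by limma, with between 315 and 929 genes at an unadjusted p under 0.05. The sum was 3217 without array 1 of AKAP12 and 9594 without array 1 of ARHGDIB at 96 h. These counts take the 48 h and 96 h arrays as independent. With a random effect shared by arrays of one target and number they were 2598 for AKAP12, 730 for ARHGDIB, 340 for CD82, 92 for CD44, 79 for KISS1, 11 for DRG1, 10 for CDH2, 6 for MAPK14, 5 for RRM1, 3 for PEBP1, 1 for BRMS1 and MAP2K6 and 0 for CDH11, own genes included. Across the 19 targets, 83 list calls were made (41 up, 42 down) by camera with the preset correlation, and 2 of them held with an estimated correlation. These were the interferon-response genes in the CDH1 and the CD44 knockdowns. These list tests took the 48 h and 96 h arrays as independent and were not repeated with the random effect. Of the 83, fry's directional test, which does not compare a list with other genes, also called 19. In the paragraphs on single targets below, genes and lists are raised or lowered against the other knockdowns, which need not hold against scramble.

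**Figure D3:**
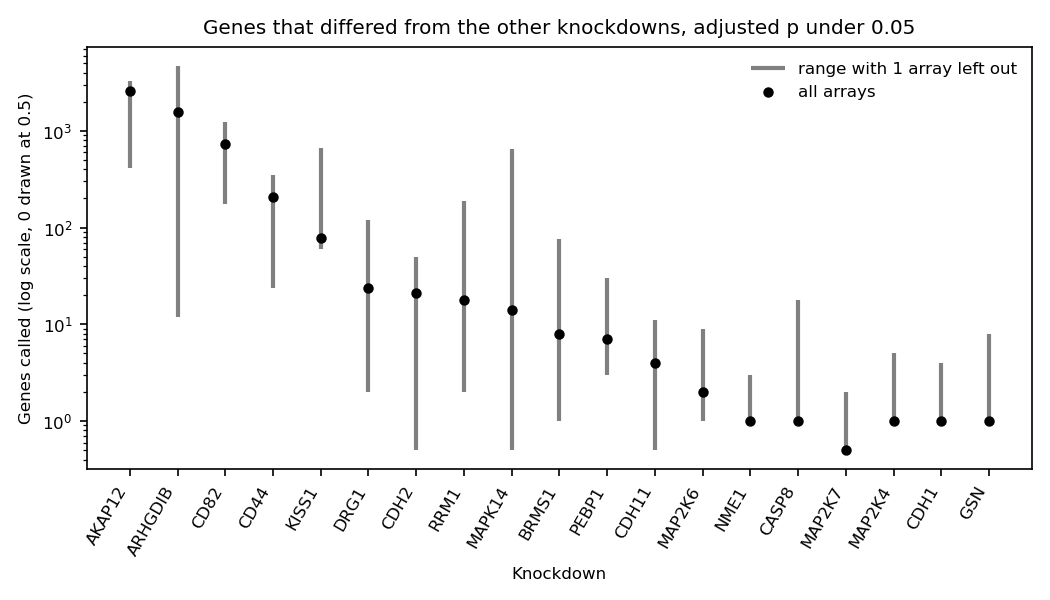
Number of genes called for each target against the other knockdowns, own gene included, on a log axis with 0 drawn at 0.5. Grey lines give the range when 1 array is left out. AKAP12 (2578) and ARHGDIB (1553) have the most, and the ARHGDIB range reaches far below its point.

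AKAP12 is a scaffold for protein kinases A and C. In AKAP12-depleted cells at 96 h (n = 2), the mitosis list fell against the other knockdowns (median -0.40, 9 of 23 genes called and 11 adjusted over the list alone). CENPE fell by 1.41 log2 units (SE 0.33), the proliferation marker MKI67 by 1.30 (SE 0.28), CENPF by 1.22 (SE 0.31) and TOP2A by 1.03 (SE 0.25). Higher were 16 of 31 oxidative phosphorylation genes (median 0.30, 18 higher and 1 lower adjusted over the list alone; COX5B 0.50, SE 0.10), 10 of 25 ribosomal protein genes (0.37, 20 adjusted over the list alone; RPS9 0.45, SE 0.10), 8 of 23 interferon-response genes (0.38, 9 higher and 1 lower adjusted over the list alone; IFI27 1.38, OASL 0.96), 5 of 20 ATF4 genes (0.42, 5; ATF5 0.48) and 4 of 9 antigen presentation genes (0.32, 5; HLA-E 0.49). Adjusted p = 0.601 to 0.634 with an estimated correlation for these 6 lists, and after quantile normalization the mitosis list alone passed. The ribosomal and oxidative phosphorylation medians shrank to 0.03 and 0.14 there (adjusted p = 0.827 and 0.0528), while the interferon, ATF4 and antigen presentation lists kept their size (0.36, 0.38 and 0.36) and missed the threshold narrowly (adjusted p = 0.0528 each).

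By single genes, the largest rises with AKAP12 siRNA were HMOX1, heme oxygenase (1.86, SE 0.51, adjusted p = 0.00728), the chemokine CCL5 (1.67, SE 0.36, adjusted p = 0.000912) and OAS1, an interferon-induced oligoadenylate synthetase (1.57, SE 0.40). The largest falls were CRISP3 (-1.78, SE 0.40), ASPM, a spindle protein (-1.69, SE 0.34), and CCDC18-AS1 (-1.68, SE 0.41). CRISP3 and CCDC18-AS1 lay below the level of the signal filter in these cells, so their sizes depend on the pseudocount. Without array 1, which had the highest GAPDH 3' to 5' ratio, 412 genes were left and all 6 of these calls ended. The remaining array gave 0.49 for HMOX1, 1.14 for CCL5, 0.42 for OAS1, -1.48 for CRISP3, -1.49 for ASPM and -0.67 for CCDC18-AS1. Against scramble at 96 h, with both arrays, HMOX1, CCL5 and OAS1 were at 1.35, 1.74 and 1.98. CRISP3, ASPM and CCDC18-AS1 were at -0.47, -0.81 and -0.62 there, with adjusted p = 0.72, 0.414 and 0.631. Of these genes OAS1 alone passed against scramble (adjusted p = 0.0498).

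CD82 siRNA (n = 4), with which the CD82 transcript itself did not pass, lowered TIMP2, an inhibitor of metalloproteinases (-1.22 log2 units, SE 0.23, adjusted p = 0.000686), the chromatin-binding PSIP1 (-1.18, SE 0.21, adjusted p = 0.000413) and HSPG2, the basement membrane proteoglycan perlecan (-1.10, SE 0.31). It raised DNAAF1, a dynein assembly factor (1.03, SE 0.20, adjusted p = 0.00108), the collagen gene COL5A2 (1.02, SE 0.23) and MVP, the major vault protein (0.90, SE 0.18). Its DNA replication list fell (median -0.08, 3 genes called and 6 adjusted over the list alone), with CDC6 at -0.58 (SE 0.14) and MCM10 at -0.46, and so did mitosis (-0.18, 0 and 0). Lists that rose were oxidative phosphorylation (0.13, 4 called, 7 higher and 1 lower adjusted over the list alone; UQCRC2 0.26, SE 0.06), metallothioneins (0.43, 1 and 6; MT1G 0.44), luminal epithelial genes (0.17, 1 and 1; TFAP2C 0.24), ribosomal proteins (0.17, 1 and 1), lysosome (0.13, 1 and 0; LAMP2 0.24) and histones (0.22, 0 and 1). Adjusted p = 0.539 to 0.876 with an estimated correlation, and of the 6 raised lists only the metallothioneins kept their call after quantile normalization (adjusted p = 0.0365). The ribosomal and oxidative phosphorylation medians shrank to 0.02 and 0.04 there and the luminal median to 0.11, while histones (0.20) and lysosome genes (0.12) nearly kept their size. HSPG2 lay below the level of the signal filter with CD82 siRNA, so its size depends on the pseudocount. Array 2 at 96 h had the highest ACTB 3' to 5' ratio of all arrays. Calls dropped to 175 without that array, ending those of MVP, PSIP1 (-0.71) and HSPG2. Without array 1 at 48 h the calls of COL5A2, MVP, TIMP2 (-0.77) and HSPG2 ended, and without array 1 at 96 h that of HSPG2. Without array 2 of ARHGDIB at 96 h there were 1223.

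Cells given CD44 siRNA, with 1 array at each time, showed interferon-response genes that rose together (median 0.54, 21 of 23 above 0, 4 called and 12 adjusted over the list alone, adjusted p = 0.0386 with an estimated correlation). IFI27 rose by 1.81 log2 units (SE 0.34, adjusted p = 0.000786), IFIT1 by 1.78 (SE 0.47) and IRF9, a subunit of the interferon-activated transcription factor, by 0.87 (SE 0.24). Cholesterol synthesis genes rose (0.22, 2 called, 4 adjusted over the list alone; MSMO1 0.60, SE 0.13), as did immediate early genes (0.33, 2 and 6; JUN 0.66, SE 0.15; ZFP36 0.50), lysosome (0.17, 0 and 0) and antigen presentation genes (0.22, 0 and 1). NRF2 targets fell (-0.26, 4 and 5), among them the aldo-keto reductases AKR1C3 (-1.12, SE 0.28), AKR1C2 (-0.73) and AKR1C1 (-0.69) and the quinone reductase NQO1 (-0.44). DNA replication (-0.27, 0 of 25 above 0, 0 and 1), mitosis (-0.18, 0 and 0) and Wnt targets (-0.30, 0 and 2) also fell. For these 8 other lists adjusted p = 0.174 to 0.729 with an estimated correlation. Outside the lists, the pseudokinase TRIB2 rose (1.61, SE 0.21, adjusted p = 7.89e-07) and CDS1, an enzyme of phospholipid synthesis, fell (-1.59, SE 0.16, adjusted p = 2.03e-09). BRINP2 (-1.97, SE 0.47) and ZNF429 (-1.74, SE 0.28) fell as well, to below the level of the signal filter, so their sizes depend on the pseudocount. Without the 96 h array 24 calls were left and IFI27 (0.94), IFIT1 (0.89), ZNF429 (-1.68) and BRINP2 (-1.53) lost theirs. BRINP2 also lost it without the 48 h array (-2.42), and without array 2 of ARHGDIB at 96 h the count was 353.

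ARHGDIB, an inhibitor of Rho GTPases, gave calls that mostly rested on a single array. The largest falls were PARD6B, a cell polarity protein (-1.54 log2 units, SE 0.29), PTP4A1, a phosphatase (-1.53, SE 0.28), and SEC23B, a vesicle coat protein (-1.48, SE 0.29). The largest rises were ELMOD3 (0.97, SE 0.33), the immediate early gene EGR1 (0.74, SE 0.18) and NUDT3 (0.66, SE 0.11; n = 4 for each). Without array 2 at 96 h, 12 calls were left, and the values became -0.35, -0.38 and -0.21 for PARD6B, PTP4A1 and SEC23B and 0.87 and 0.45 for ELMOD3 and EGR1, none of these 5 called. NUDT3 kept its call without any 1 array (0.61 to 0.72, highest adjusted p = 0.0166). Without array 1 at 96 h there were 4664. The ELMOD3 call also ended without either 48 h array (adjusted p = 0.105 and 0.229) and, by a small margin, in 20 further fits that each left out an array of another group. EGR1 also lost its call without array 2 at 48 h (0.71). Other probe sets of PARD6B, PTP4A1 and SEC23B were between -0.28 and 0.21, with both signs for each gene. No gene list was called.

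RRM1 depletion (n = 4) raised p53 targets (median 0.38, 22 of 22 above 0, 1 called and 13 adjusted over the list alone, adjusted p = 0.0698 with an estimated correlation). DDB2, a DNA damage recognition protein, rose by 0.58 log2 units (SE 0.11, adjusted p = 0.00784). Interferon-response genes rose (0.35, 22 of 23 above 0, 1 and 9; PARP9 0.62, SE 0.13; adjusted p = 0.0698 with an estimated correlation) and mitosis genes fell (-0.22, 1 of 23 above 0, 0 and 6, adjusted p = 0.313 with an estimated correlation). Lysosome (0.13, 18 of 18 above 0, 0 and 0), NF-kB (0.23, 0 and 0), NRF2 (0.14, 0 and 0), invasion (0.18, 0 and 0) and antigen presentation genes (0.19, 0 and 0) rose, with adjusted p between 0.137 and 0.313 with an estimated correlation. The targeted suppressors as a list were at 0.17 (RRM1 itself the 1 fall called; 3 adjusted over the list alone, 2 of them higher; adjusted p = 0.0765 with an estimated correlation), raised in part because the comparison holds each gene's own knockdown, and at 0.09 with each of the 14 others read without it. Ribosomal protein and oxidative phosphorylation genes fell (-0.06 each, 0 and 0), with adjusted p = 0.71 and 0.496 with an estimated correlation. After quantile normalization the ribosomal (median -0.01, adjusted p = 0.189) and NF-kB calls (adjusted p = 0.058) ended. AOX1, aldehyde oxidase (1.12, SE 0.18, adjusted p = 0.000791), CAPN8, a calpain (1.11, SE 0.20), and SHC4 (0.95, SE 0.20) rose, and MALRD1 (-0.82, SE 0.14), TNFAIP8L1 (-0.56, SE 0.12) and STX8 (-0.46, SE 0.10) fell. None of these genes passed at either time alone against scramble. There MALRD1 was at -0.35 at 48 h and -0.15 at 96 h, and AOX1 at 1.13 and 1.32. Against the other knockdowns AOX1 kept its call without any 1 array. The others lost theirs without array 1 at 48 h (CAPN8 1.05, STX8 -0.38) or array 1 at 96 h (CAPN8 0.70, STX8 -0.36), and SHC4 and TNFAIP8L1 also without array 2 at 48 h. The number of calls was 2 without array 1 at 48 h and 187 without array 2 at 96 h.

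KISS1 siRNA at 48 h (n = 2) lowered SLC11A1, a metal transporter (-1.71 log2 units, SE 0.32, adjusted p = 0.00466), GPR65, a proton-sensing receptor (-1.27, SE 0.31), and FABP5, a fatty acid binding protein (-1.16, SE 0.22), and raised BCORL1 (0.82, SE 0.20), TPRG1L (0.66, SE 0.17) and RAB40B (0.65, SE 0.16). SLC11A1 and GPR65 lay below the level of the signal filter in these cells, so their sizes depend on the pseudocount. Another probe set of SLC11A1 was at -0.28 (SE 0.52), another of RAB40B at 0.05, and others of BCORL1 at 0.09 and 0.03. Cholesterol synthesis genes rose (0.15, 15 of 18 above 0, 0 called and 0 adjusted over the list alone; adjusted p = 0.948 with an estimated correlation). All but BCORL1 lost their calls without array 2 (GPR65 -0.45), BCORL1 lost its call without array 1 (0.53), and the count was 662 without array 1. TPRG1L also lost it in 41 and RAB40B in 4 fits that each left out an array of another group. DRG1 depletion (n = 4) lowered TFPI2, a protease inhibitor (-1.01, SE 0.18, adjusted p = 0.00204), the lysosomal protease LGMN (-0.85, SE 0.14) and ZDHHC12 (-0.85, SE 0.15). ZDHHC23 (0.40, SE 0.09) and the chaperone DNAJB11 (0.31, SE 0.07) rose. Its p53 targets fell (-0.15, 0 called, 1 adjusted over the list alone) and histones (0.24, 0 and 1) and mitosis genes (0.12, 0 and 0) rose, with adjusted p = 0.882, 0.882 and 0.945 with an estimated correlation. All 5 gene calls ended without array 1 at 48 h (TFPI2 -0.86) or array 1 at 96 h (TFPI2 -0.57), and ZDHHC23 also without array 2 at 48 h. There were 2 calls without array 1 at 96 h and 121 without array 2 at 96 h.

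CDH2 siRNA (n = 3) lowered CYB5A, cytochrome b5 (-1.21 log2 units, SE 0.14, adjusted p = 1.91e-07), EHD2, a membrane-trafficking protein (-1.28, SE 0.19), and PTPRN2 (-1.42, SE 0.29), and raised NPEPL1 (0.48, SE 0.09). Without its only 48 h array there were 0 calls, and CYB5A was at -0.51 and EHD2 at -0.77. PTPRN2 and NPEPL1 also lost their calls without array 1 at 96 h, and there were 50 calls without array 2 at 96 h. Another probe set of EHD2 was at 0.04 and another of NPEPL1 at -0.32. PTPRN2 lay below the level of the signal filter with CDH2 siRNA, so its size depends on the pseudocount. MAPK14 siRNA (n = 4) lowered the estrogen-response genes as a list (-0.26, 0 of 24 above 0, 0 called and 6 adjusted over the list alone, adjusted p = 0.0601 with an estimated correlation). ERK feedback genes (-0.20, 0 and 2) and immediate early genes (-0.08, 0 and 2) also fell, and oxidative phosphorylation genes rose (0.12, 31 of 31 above 0, 0 and 0), with adjusted p = 0.111, 0.232 and 0.545 with an estimated correlation. HLA-DRB1, an antigen-presenting molecule, rose by 0.91 (SE 0.16, adjusted p = 0.00452) and KCNF1, a potassium channel subunit, fell by 1.06 (SE 0.18). KCNF1 lay below the level of the signal filter with MAPK14 siRNA. There were 0 calls without array 2 at 48 h, 655 without array 1 at 96 h, and HLA-DRB1 (0.60) lost its call without array 2 at 96 h. For the remaining targets the largest changes were SALL4, a stem cell transcription factor, in the BRMS1 knockdown (-0.98, SE 0.21), PROM2 in the PEBP1 knockdown (-0.92, SE 0.17), CASKIN1 in the MAP2K6 knockdown (-0.84, SE 0.17) and CBX6, a Polycomb protein, in the CDH11 knockdown (-0.54, SE 0.10). CBX6 lost its call without array 2 at 48 h (-0.34) or at 96 h (-0.35), PROM2 without array 1 at 48 h (-0.73) or array 2 at 96 h (-0.96), and SALL4 without array 1 at 48 h (-0.83), array 2 at either time or, by a small margin, 1 array of the CDH1 or MAP2K6 knockdown at 48 h. CASKIN1 was called in 28 of the 77 fits with 1 array left out (lowest size -0.43, without array 1 at 96 h). BRMS1 had 77 genes called, own gene included, without its array 1 at 48 h, and PEBP1 30 without its array 1 at 96 h. With the shared random effect the calls of CBX6, SALL4 and CASKIN1 ended (adjusted p = 0.111, 0.189 and 0.382), as did those of HSPG2 with CD82 siRNA, PTPRN2 with CDH2 siRNA, ELMOD3 with ARHGDIB siRNA, IFIT1 with CD44 siRNA, ZDHHC23 and DNAJB11 with DRG1 siRNA and SHC4, TNFAIP8L1 and STX8 with RRM1 siRNA.

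Interferon-response genes also moved in knockdowns with few or no single-gene calls. With CDH1 siRNA (n = 3) 0 of the 23 lay above 0 (median -0.34, 0 called and 6 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation). In the CASP8 knockdown 1 of 23 did (-0.31, 0 and 8, adjusted p = 0.0688 with an estimated correlation). They fell with NME1 (-0.13), BRMS1 (-0.13) and MAP2K7 siRNA (-0.15) and rose with MAP2K4 siRNA (0.14; 0 called and 0 adjusted over the list alone in each), with adjusted p between 0.309 and 0.984 with an estimated correlation, and the BRMS1 call ended after quantile normalization (adjusted p = 0.0562). MAP2K7 siRNA also lowered cholesterol synthesis (-0.17, 2 of 18 above 0, 1 adjusted over the list alone, adjusted p = 0.0852 with an estimated correlation), YAP targets (-0.19, 0), immediate early (-0.10, 4 lower and 1 higher), invasion (-0.15, 2), cell junction (-0.07, 0) and metallothionein genes (-0.18, 0), for which adjusted p was 0.243 to 0.309 with an estimated correlation. MAP2K6 siRNA raised YAP targets (0.16) and CDH2 siRNA lowered cholesterol synthesis (-0.14) and raised p53 targets (0.14; adjusted p = 0.0539 after quantile normalization). Mitosis genes rose in the NME1 (0.13), BRMS1 (0.22), MAP2K4 (0.08) and PEBP1 (0.09) knockdowns and DNA replication genes with NME1 (0.10) and BRMS1 siRNA (0.11). In these last lists, 0 genes passed adjusted over the list alone, with adjusted p = 0.6 to 0.984 with an estimated correlation.

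The remaining list calls had 0 members called. NME1 siRNA lowered histones (-0.13), NF-kB (-0.20) and oxidative phosphorylation genes (-0.05) and raised ERK feedback genes (0.18). Lysosome genes fell with BRMS1 (-0.10), CDH1 (-0.11) and CASP8 siRNA (-0.09), and antigen presentation genes with CDH1 (-0.16), CASP8 (-0.16) and PEBP1 siRNA (-0.18). PEBP1 siRNA also lowered p53 targets (-0.14) and raised unfolded protein response genes (0.07). CASP8 siRNA raised estrogen-response genes (0.11), and MAP2K4 siRNA raised ATF4 genes (0.11) and lowered immediate early genes (-0.11, 3 adjusted over the list alone and 0 in each other list of this paragraph). Oxidative phosphorylation genes fell with CDH1 siRNA (-0.12), and heat shock genes fell with GSN siRNA (-0.09). Ribosomal protein genes fell with CDH1 (-0.19), CASP8 (-0.09) and GSN siRNA (-0.10), but their medians were 0.000324, 0.000591 and 0.02 after quantile normalization. For all of these adjusted p = 0.479 to 0.99 with an estimated correlation. Quantile normalization also ended the calls of oxidative phosphorylation with CDH1 (-0.03, adjusted p = 0.316) and NME1 siRNA (-0.01, adjusted p = 0.282), heat shock with GSN siRNA (-0.05, adjusted p = 0.36) and, narrowly, antigen presentation and estrogen response with CASP8 siRNA (adjusted p = 0.0501 and 0.052). The mesenchymal, basal mammary, apoptosis regulator and small RNA machinery lists were called in none of the 25 comparisons, with lowest adjusted p = 0.0506, 0.0862, 0.0826 and 0.0979. Fibroblast, leukocyte and endothelial markers (3, 3 and 2 genes above the filter) were not tested.

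**Figure D4:**
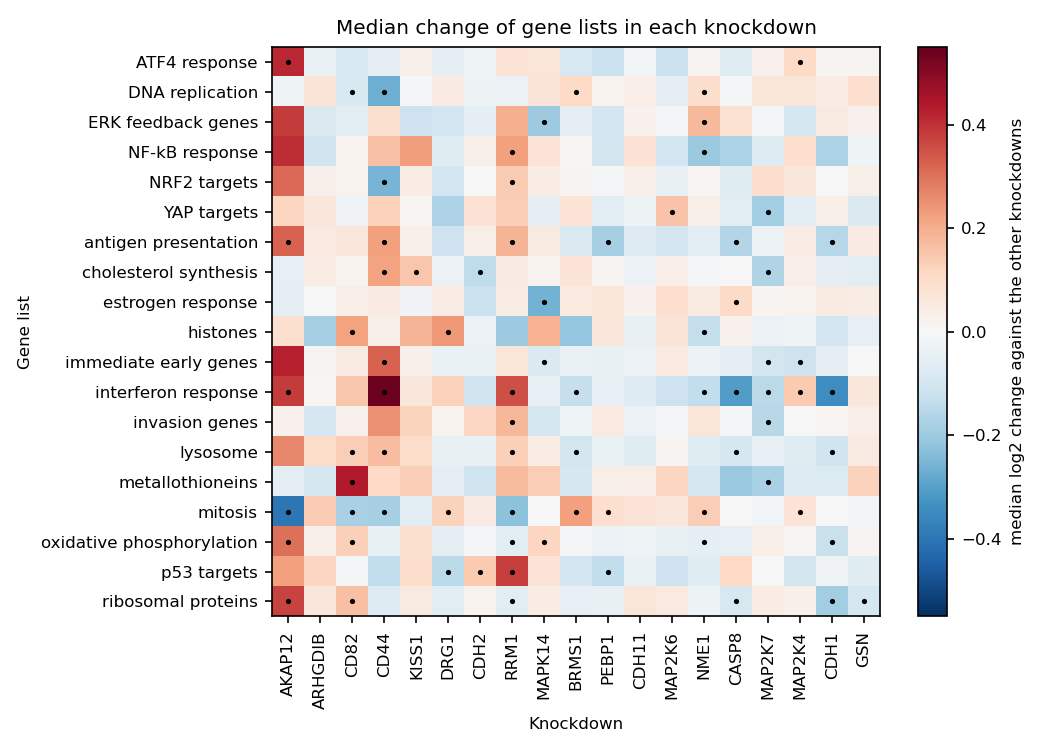
Median log2 change of 19 gene lists (rows) in each knockdown (columns) against the other knockdowns, with dots on the calls made with the preset correlation. Interferon-response genes range from -0.34 with CDH1 siRNA to 0.54 with CD44 siRNA, and p53 targets are highest with RRM1 siRNA (0.38).

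Arrays of the same target resembled each other more than arrays of different targets. Within a time the mean correlation across genes of their deviations was 0.0552 for 32 same-target pairs and -0.0273 for 1090 other pairs, a difference of 0.0825 (permutation p = 0.0001, one-sided, the smallest that 10000 permutations can give). Across times it was 0.119 for 61 pairs and -0.00434 for 1095 (difference 0.123, permutation p = 0.0001, also the smallest possible). Much of the latter came from arrays with the same number. Over the 30 pairs with different numbers it was 0.0312 (difference 0.0355, permutation p = 0.0155 with arrays of one target and number kept together, one-sided). Within a time the AKAP12 pair was highest (0.403), while KISS1 (-0.109), DRG1 (-0.0205) and MAP2K6 (-0.00975) lay below 0. Across times the only CD44 pair, which shares a number, was at 0.325, and the 2 CD82 pairs that share a number averaged 0.388. Between targets, AKAP12 and KISS1 had the highest correlation (0.39), although the 2 KISS1 arrays did not resemble each other, and NME1 and CD82 the lowest (-0.343). The MAP2K4, MAP2K6, MAP2K7 and MAPK14 kinases (mean -0.0416 over 6 pairs) and the CDH1, CDH2 and CDH11 cadherins (0.131 over 3 pairs) together were no closer than other pairs by the test (difference 0.0718, permutation p = 0.0778 from 100000 permutations, one-sided).

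Time after transfection changed 1757 genes in the knockdown cells (1096 higher and 661 lower at 96 h than at 48 h, over 17 targets). These counts take the 48 h and 96 h arrays as independent. A block of target by number, or a random effect shared by such arrays, called more genes, as given with the settings below. Falling genes included S100A9, a calprotectin subunit (-1.09 log2 units, SE 0.19), CYP26A1, which degrades retinoic acid (-1.06, SE 0.15), DHRS2 (-1.05, SE 0.11), the transcription factor SOX9 (-0.97, SE 0.11), ALDH1A3, which makes retinoic acid (-0.94, SE 0.14), TGM2, a transglutaminase (-0.94, SE 0.13), CEACAM5, an adhesion molecule (-0.81, SE 0.10), and ZG16 (-0.81, SE 0.11). Rising genes included SPMIP5 (1.05, SE 0.13), SSTR5-AS1 (0.80, SE 0.18), FBXO17 (0.78, SE 0.20), MFAP2, a microfibril protein (0.76, SE 0.08), SECTM1 (0.68, SE 0.16), FKBP1B (0.67, SE 0.12), SHH, the hedgehog ligand (0.66, SE 0.07), and RAMP3, a receptor subunit (0.66, SE 0.10). SHH rose in 17 of 17 targets (adjusted p = 2.45e-08), S100A9 fell in 16 (adjusted p = 6.76e-05), and FBXO17, which rose in 15, was the least uniform of the 16. All 16 calls held without any 1 array, and another probe set of CEACAM5 was at 0.05. At the time of their lower level, SPMIP5, SSTR5-AS1, FBXO17, SECTM1, FKBP1B, CYP26A1 and ZG16 lay below the level of the signal filter. Fewer cells were seeded for 96 h, so time and seeding went together.

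**Figure D5:**
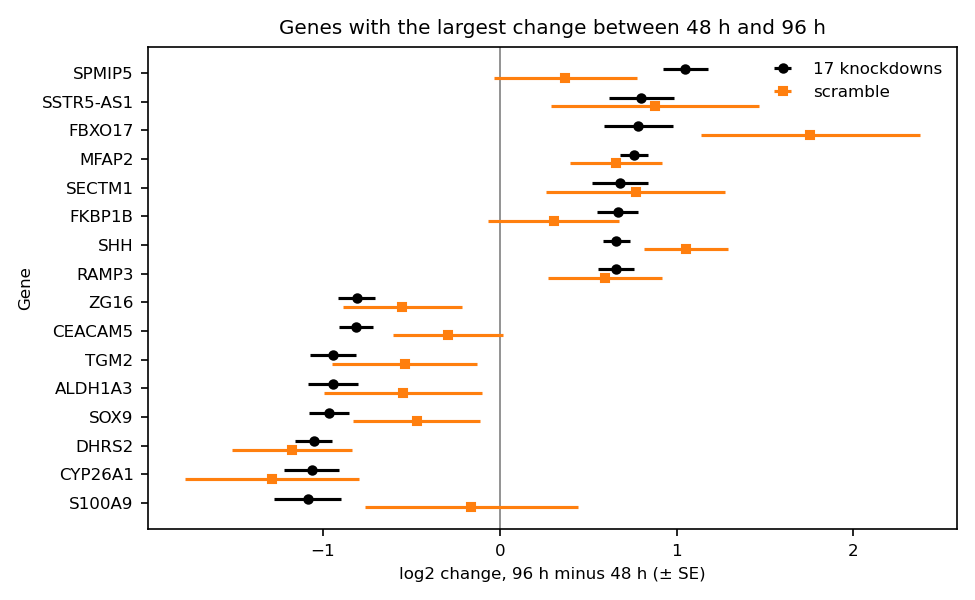
Log2 change from 48 h to 96 h of the 16 named genes, with the standard error as bars, in the knockdowns (black, 17 targets) and in scramble cells (orange, 3 arrays per time). DHRS2 lies at -1.05 in the knockdowns and -1.17 in scramble, and FBXO17 at 0.78 and 1.76.

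Among the lists, 9 of 11 histone genes (median 0.31, 10 adjusted over the list alone; H2AC8 0.42, SE 0.09) and 13 of 23 interferon-response genes (0.26, 13 higher and 2 lower adjusted over the list alone; IFIT1 0.60, SE 0.17; HERC5 0.48; IFIT2 0.45; IFITM1 0.41) rose by 96 h. Mitosis (-0.12, 5 called and 8 adjusted over the list alone; CDK1 -0.34, SE 0.10), DNA replication (-0.13, 6 and 6; RFC3 -0.24, SE 0.06), NRF2 (-0.09, 7 called, 8 adjusted over the list alone; AKR1B10 -0.48), hypoxia and glycolysis (-0.04, 5 and 5; HK2 -0.51), cholesterol synthesis (-0.04, 4 and 4; SQLE -0.23) and NF-kB genes (-0.11, 2 called, 3 adjusted over the list alone; TNFAIP3 -0.53, RELB -0.50) fell, as did ribosomal protein genes (-0.07, 0 and 0). For the ribosomal list adjusted p = 0.764 with an estimated correlation and for the 8 others 0.503. After quantile normalization the ribosomal (median -0.00341, adjusted p = 0.551) and cholesterol calls (adjusted p = 0.0616) ended, and the hypoxia and glycolysis median was -0.0072.

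In scramble cells 0 genes passed for time by limma (1207 at an unadjusted p under 0.05, n = 3 against 3). With the replicate number as a block, 84 did (44 higher, 40 lower), but pairing showed for number 2 alone. There were 124 without array 3 at 96 h, 2 without array 1 or 1 without array 2 at 48 h, and 2 without either KISS1 array. Of the 1757 genes called in the knockdowns, 1379 (78.5%, against 50% by chance) had the same sign in scramble, and across genes the correlation was 0.344, where genes are not independent replicates. Ribosomal protein genes rose in scramble cells (0.31, 25 of 25 above 0, but -5.66e-05 after quantile normalization), with histones (0.42), oxidative phosphorylation (0.19) and antigen presentation genes (0.33), and cholesterol synthesis genes fell (-0.07). Of these, 2 antigen presentation genes passed adjusted over the list alone and 0 of the other lists. For these 5 lists adjusted p = 0.857 with an estimated correlation, and after quantile normalization the ribosomal, oxidative phosphorylation (adjusted p = 0.0762) and cholesterol calls (adjusted p = 0.0906) ended. With the block, mitosis genes also fell (adjusted p = 0.0373, against 0.0573 without it) and the same 5 lists kept their calls.

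Scramble cells were also set against untreated cells (n = 3 each). The latter have no labelled time, so transfection and culture time are not separated. At 48 h MYC was higher (1.06 log2 units, SE 0.20, adjusted p = 0.019) and RSRP1 (-1.10, SE 0.22), HIRA, a histone chaperone (-0.91, SE 0.17), and KHDC4 (-0.59, SE 0.12) lower. At 96 h ABCG1, a cholesterol exporter (1.42), and SLC3A2, an amino acid transporter subunit (0.90, SE 0.18, adjusted p = 0.0293), were higher and RAD50 (-1.32), TRIP11 (-1.28), MYCBP2 (-0.83) and SEC63 (-0.65) lower. Over both times SLC3A2 (0.85, SE 0.16, adjusted p = 0.0233) and HIRA (-0.78, SE 0.15, adjusted p = 0.0233) passed. Both lost that call without array 2 of scramble at 96 h or array 1 or 3 of the untreated cells. SLC3A2 also lost it without array 2 of scramble at 48 h, and HIRA with the shared random effect (adjusted p = 0.0987). Other probe sets changed less over both times (RAD50 -0.34 and -0.11 against -0.83, SEC63 -0.22 to -0.04 against -0.46, TRIP11 -0.66 and 0.17 against -0.87). At an unadjusted p under 0.05 there were 1296 and 1532 genes.

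Single arrays moved the counts of called genes strongly. At 48 h, 4 genes became 0 without array 3, 2 without array 1 and 27 without array 2 of the untreated cells. The 48 h count was 1 without array 2 of scramble at 48 h, 8 without its array 3, 17 without array 2 of scramble at 96 h, and 2 in most of the 42 fits that moved it. At 96 h, 6 became 0 without array 1 or array 2 of scramble, 0 without array 1 or 3 and 1 without array 2 of the untreated cells. That count rose to 618 without array 3 of scramble, 71 without either KISS1 array, 35 without either ARHGDIB array of 96 h, and 23 without array 2 of scramble at 48 h.

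Against untreated cells, mitosis genes of scramble cells fell at 48 h (median -0.41, 1 of 23 above 0, 1 adjusted over the list alone) and at 96 h (-0.46, 0 of 23, 11 adjusted over the list alone), with adjusted p = 0.422 and 0.328 with an estimated correlation. DNA replication genes fell at both times (-0.23 and -0.17, 0 and 1 adjusted over the list alone; adjusted p = 0.525 and 0.767 with an estimated correlation). ERK feedback genes rose at 48 h (0.28) and 96 h (0.38), immediate early genes (0.22 and 0.32), ATF4 (0.17 and 0.32), TGF-beta (0.27 and 0.33), hypoxia and glycolysis (0.15 and 0.27), p53 (0.28 and 0.19) and NRF2 genes (0.08 and 0.23) likewise. Adjusted over the list alone, ERK feedback had 1 and 3, immediate early 2 (1 of them lower) and 3, ATF4 1 and 1, and the rest 0. For these lists adjusted p = 0.422 with an estimated correlation at 48 h and 0.0877 to 0.767 at 96 h. At 48 h histones (-0.47, 5 adjusted over the list alone), estrogen-response (-0.11, 0), oxidative phosphorylation (-0.14, 0) and ribosomal protein genes (-0.31, 0; 0.02 after quantile normalization) fell and interferon-response (0.21, 0), YAP (0.30, 0) and invasion genes (0.30, 0) rose, with adjusted p = 0.422 with an estimated correlation. Of these the ribosomal, estrogen-response, oxidative phosphorylation, YAP and invasion calls ended after quantile normalization (adjusted p = 0.203, 0.146, 0.162, 0.0739 and 0.0648). At 96 h antigen presentation genes rose (0.36, 2) and cholesterol synthesis genes fell (-0.08, 0), with adjusted p = 0.328 and 0.513 with an estimated correlation. Without both scramble arrays numbered 2, mitosis at 96 h kept its call (-0.22, adjusted p = 1.18e-06, and 0.584 with an estimated correlation), and at 48 h interferon-response (0.30), ribosomal protein (-0.33) and oxidative phosphorylation genes (-0.12) did, with adjusted p = 0.601, 0.614 and 0.776 with an estimated correlation. In that setting the p53 and ATF4 medians at 48 h were -0.04 and -0.10 and DNA replication was at 0.06, none of them called.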

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

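Chosen after the result was seen were the 3 tests of the ARHGDIB array, the shared-batch and RNA quality tests of the scramble arrays numbered 2, the RNA quality test of the AKAP12 knockdown, and the splits that keep arrays of one number together.

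The difference between a knockdown and the other knockdowns was tested for change between 96 h and 48 h. It passed for 692 genes with ARHGDIB siRNA and for 1 gene each with CD82, MAP2K4 and CD44 siRNA. Those of the first 2 were PPP5C with CD82 siRNA (-1.06, SE 0.20, adjusted p = 0.0325) and SDC3 with MAP2K4 siRNA (2.23, SE 0.41, adjusted p = 0.0209), each chosen after its values were seen. CD44 has 1 array at each time and no spread of its own, so its gene is not read as a difference between times. CDH1 in its own knockdown was lower at 96 h by a difference of -0.99 log2 units against the other knockdowns, a value that rests on a single 96 h array, so its p value is not given. No group had 4 to 10 samples, so no group was tested for a sample far from the others.

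Most ARHGDIB calls rested on array 2 at 96 h. In the 3 other ARHGDIB arrays the same genes deviated in that direction by 0.659% of its median deviation of 1.64, which argues against loss of ARHGDIB as the cause, and 93.1% as many calls came after quantile normalization (1446 against 1553), which argues against the authors' scaling. Of other probe sets for these genes, 60.6% deviated the same way in that array, by a median of 0.19 against 1.77, compared with 89.9% for the AKAP12 knockdown and 76.9% for CD82 at 96 h. A fault of the array that acts on single probe sets therefore stays open.

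The scramble arrays numbered 2 deviated together at 48 h and 96 h, with ATF3 (3.86 above the other scramble arrays at 48 h and more at 96 h), GDF15 (2.53 and 3.45), SLC7A11 (2.61 and 2.51) and CHAC1 (2.26 and 2.26) high and IFIT1 low (-2.55 and -2.36). A batch shared by all arrays numbered 2 is argued against by a median correlation of -0.0132 with the knockdown arrays of that number. The GAPDH 3' to 5' ratio was 0.967 SD above that of the other scramble arrays, with an SE of 0.866 SD for 2 arrays against 4, so RNA quality cannot be told apart from other sources with so few arrays. A mislabelled knockdown stays open, since RRM1 was lower in both arrays (-1.02 and -0.771). Against RRM1 siRNA in particular, their profile correlated with that knockdown at 0.182, less than with AKAP12 (0.28), and IFIT1 was low where RRM1 siRNA raised interferon-response genes. No biological explanation was tested.

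Genes with long loci fell in the AKAP12 knockdown, with a median locus of 67.6 kb for lowered and 14.6 kb for raised genes against 29.1 kb for all (12078 of 12088 with a length). The rank correlation of change and length was -0.32, below the lowest of the other targets (-0.27, MAPK14) by -0.0471, which does not separate it from a length effect present in other arrays. It appeared in both arrays (-0.35 in array 2 and -0.216 in array 1), which argues against 1 array alone as the source. The lower GAPDH ratio of the AKAP12 arrays was -0.110 from the highest of the other knockdown arrays at 96 h, so RNA quality cannot be told apart with 2 arrays. Loss of AKAP12 stays open and untested.

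The calls were also counted after the samples were regrouped, with 100 splits including the real one. Chance can be excluded for the targets that fell (13, highest other 2, 1 split as large) and for time in the knockdowns (1757, highest other 1, 1 split). For the calls against the other knockdowns (5259, highest other 3918, 1 split) these splits treat the 48 h and 96 h arrays as independent, while same-number arrays of a target resembled each other. When such arrays were kept together, 6 of 100 splits were as large (highest other 8215), so their dependence remains a possible source of that count. It cannot be excluded for the calls against scramble (1525, highest other 3325, 10 splits), all knockdowns against scramble at 48 h (1, highest other 112, 26 splits) or 96 h (6, highest other 2408, 16 splits). For the difference of times (0, highest other 532, 100 splits) and genes higher in at least 10 knockdowns (0, highest other 0, 100 splits) the real count is 0, which every split reaches, so the splits carry no information. Splits that call several times more genes than the real one point to a structure of the samples. For 3 against 3 arrays the 10 splits are too few. There the real and highest other values were 4 and 7 for scramble against untreated at 48 h (2 splits as large), 6 and 1 at 96 h (1 split), and 0 and 885 for time in scramble (10 splits, again reached by every split).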

How the results depend on the processing

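Alternatives chosen after seeing the data were those that leave out both scramble arrays numbered 2, these with ARHGDIB array 2 of 96 h, the AKAP12 and ARHGDIB knockdowns, or the AKAP12, KISS1 and CD44 knockdowns, similarity without ARHGDIB array 2 of 96 h, similarity across times over arrays with different numbers alone (0.0355), and a random effect shared by arrays of one target and number. The count of targets that fell, 13, was 13 or 14 throughout, and the similarity differences and the family difference kept their side of the threshold. The cause was not tested for any change below, except where fewer samples or genes entered the test by construction. Changes of more than 1.5 times follow by setting, for calls summed against scramble (1525 with the settings of the report), all knockdowns against scramble at 48 h (1) and 96 h (6), the difference of times (0), genes higher in at least 10 knockdowns (0), calls summed against the other knockdowns (5259), scramble against untreated at 48 h (4) and 96 h (6), and time in scramble (0) and in the knockdowns (1757). A pseudocount of 1 gave 1 for time in scramble. Without a filter, calls against scramble were 1010, the 96 h average 0 and scramble against untreated at 48 h 2. With the upper 30% of probe sets the 48 h average was 0 and scramble against untreated at 96 h 19. The mean of all probe sets gave 852 against scramble, 0 and 0 for the averages, 3477 against the other knockdowns, and 1 and 2 for scramble against untreated. Without a variance trend the last pair was 2 and 0. Array weights gave 741 against scramble, 4 and 30 for the averages, 3 for the difference of times, 2731 against the other knockdowns, 91 and 312 for scramble against untreated and 72 for time in scramble. A replicate block gave 2879 against scramble, 2 and 432 for the averages, 2 genes higher and 1 lower in at least 10 knockdowns and 27 for scramble against untreated at 96 h. A block of target by number gave 84 for time in scramble and 2694 in the knockdowns, where 11 of 14 targets had a same-number correlation over 0.1 (43 of 482 pairs of different targets did), and 11 lists in place of 9. The random effect (correlation 0.277) gave 383 against scramble, 37 for time in scramble and 2822 in the knockdowns, with 3881 against the other knockdowns, and 1525 was reached by 32 of 100 splits that kept such arrays together. With the samples of the comparison alone, calls against scramble were 12, both averages 0, and scramble against untreated 1 and 0. With untreated cells as the control, calls were 2376 and the averages 0 and 3, and MYCBP2 (-0.25), MTERF2 (-0.13) and MYC (0.22) reversed. Leaving out both scramble arrays numbered 2 gave 329, averages of 0 and 1, and 1 and 0 for scramble against untreated. Leaving out ARHGDIB array 2 of 96 h as well gave 635, then 0 and 1, and 1 and 0. Without the AKAP12 and ARHGDIB knockdowns the averages were 2 and 252 and scramble against untreated at 96 h 33. Without AKAP12, KISS1 and CD44 the 96 h average was 173, scramble against untreated at 96 h 89 and time in scramble 3. Of 66 list calls in the 6 shared comparisons, 0 held with an estimated correlation, fry called 13 of them (15 lists in all) and 25 were called without both scramble arrays numbered 2. Of 83 for single targets, 2 held with an estimated correlation and fry called 19 of them (33 lists in all). After quantile normalization 37 of the 149 calls were lost.

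With each array left out in turn, the lowest and highest values were 13 and 14 for targets that fell, 579 (scramble 48 h array 2) and 5071 (ARHGDIB 96 h array 1) for calls against scramble, 0 and 2 for the 48 h average, 0 and 1040 (scramble 96 h array 3) for the 96 h average, 0 and 96 for the difference of times, 0 and 1 for genes in at least 10 knockdowns, and 3217 (AKAP12 array 1) and 9594 (ARHGDIB 96 h array 1) against the other knockdowns. They were 0 and 27 (untreated array 2) for scramble against untreated at 48 h, 0 and 618 at 96 h (scramble 96 h array 3), 0 and 124 for time in scramble (scramble 96 h array 3), and 1596 and 2559 for time in the knockdowns. Similarity without ARHGDIB array 2 of 96 h was 0.0835 within and 0.124 across times. Of 82 named values, 80 kept direction and side of the threshold after quantile normalization, 73 without a filter (9 lost their call), 69 with the random effect (13 lost), 62 with array weights (12 lost, 8 gained) and 61 of 74 with the mean of probe sets (13 lost). None reversed with an array left out. With array median signals between 59.6 and 80.8, the pseudocount of 16 compresses changes of dim genes.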

Other observations

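The test of replicate numbers was chosen after the result was seen. No further test was made for the other values in this part, where calls are those of the comparisons above.

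CARMIL3, which was above scramble in 19 of 19 knockdowns, had the largest mean change of the recurrently higher genes (0.82), and NDRG1 that of the recurrently lower genes (-0.87, below scramble in 19 of 19). RCN1 averaged -0.83 and was also among the genes highest in the scramble arrays numbered 2 (2.79 at 48 h and 2.66 at 96 h above the other scramble arrays). HMOX1 was high in those arrays as well (2.30 and 2.04).

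In scramble cells the named time genes had the same sign as in the knockdowns, none called, with FBXO17 at 1.76 (SE 0.62), SHH at 1.05 (SE 0.24), CYP26A1 at -1.29 (SE 0.49) and S100A9 at -0.16 (SE 0.60).

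Arrays of a target with the same number at 48 h and 96 h resembled each other more than arrays with different numbers, in 14 of 14 targets (mean correlation 0.192 against 0.0313, difference 0.161, exact one-sided p = 6.10e-05 by sign changes). The number may mark a shared culture or a shared siRNA sequence, a hypothesis that the test could not split, since the labels do not say which sequence each array had.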
